A study of Mus musculus with 8 samples.

How the data were processed

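Total RNA from 2 samples of mouse embryonic fibroblasts, 3 iHep lines and 3 samples of primary hepatocytes was hybridized to 8 Affymetrix perfect-match 3' expression arrays of the mouse genome, 1 array per sample. The deposited values are log2 signals per probe set, made by the authors with robust multi-array averaging (RMA) in Partek, the versions of which are not given in the sources used here. Values were used as deposited, with no further transformation in the main comparisons. The table held 45141 probe sets, of which 104 were controls, 28898 carried 1 gene symbol, 551 carried several and 15692 carried none. Probe sets with 1 symbol covered 17097 genes, and for the 7180 genes with more than 1 probe set the probe set with the highest mean over the 8 arrays was used. No symbol had to be updated. An array has no sequencing depth, and the number of arrays limits the precision.

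Samples were grouped by cell type into MEF (n = 2), iHep (n = 3) and PH (n = 3). The iHep group holds lines made with different factor sets, so its spread includes differences between factors. Line names and replicate numbers were taken from the sample titles. A linear model with 3 groups was fitted to all 8 arrays with lmFit and eBayes of limma 3.58.1 in R 4.3.3, leaving 5 residual degrees of freedom. The comparisons were PH against MEF, iHep against MEF and iHep against PH, each two-sided, with p-values adjusted by Benjamini and Hochberg over 17097 genes. A gene passed at an adjusted p under 0.05 with a log2 difference of at least 1 in either direction, a 2-fold difference. Errors are standard errors of the model, which pools the spread within all 3 groups. Differences between lines therefore enter the error of PH against MEF as well. The single-array comparisons of lines give differences only, counted at 2 or more on the log2 scale, a 4-fold difference. Tables were read with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots were drawn with matplotlib 3.10.9.

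Gene lists, 30 in all with 561 genes, of which 493 were on the array, were tested with camera in limma at a preset correlation of 0.01 between genes, with adjustment over the 90 tests of 3 comparisons. Each was also tested with the correlation estimated from the data and with fry, and its members were also adjusted over the list alone. Several lists share genes, such as the epithelial, cholangiocyte and fetal liver lists. For pairs of lines the median difference of a list was placed among 10000 random lists matched on mean value in 20 bins. The position of a gene between MEF and PH was 100 times the iHep minus MEF difference over the PH minus MEF difference of log2 means, for genes that passed between MEF and PH. The correlation and covariance across genes of the differences from MEF were set beside 50 simulations with unchanged groups that shared the MEF arrays as here.

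The groups, models, thresholds, lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule named, for each tested comparison, the 10 genes with the largest rise and the 10 with the largest fall among genes that passed and whose groups did not overlap. It added the 10 highest and 10 lowest genes apart from both other groups, ranked by the smaller of their differences, the 8 largest differences in each direction for each pair of lines, the 5 transduced factors, and up to 4 members with the largest differences of each list described. Symbols that are only clone names counted in the ranking but were not named.

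Alternatives fixed in that way were the mean of all probe sets of a gene, leaving out probe sets that can bind several transcripts, leaving out dim genes (no value over the value at percentile 40, 4.09, which removed 1717 genes), quantile normalization, subtracting array medians, a trended and robust variance, each line as its own group, models of only the compared groups, stricter thresholds, a block by submission order, a block by replicate number, and leaving out each array. Other alternatives were chosen after seeing the data. A block was set by the level of the bacterial control probe sets, cut at the widest gap. A second block used that level after subtracting array medians, cut at the middle of its range, and was added when its result had already been seen. The rest were averaging PH 1 with PH 2, quantile normalization without PH 3, and lists without PH 3 and each MEF array in turn. They also held a crossed pairing of PH with MEF, and the overlap of the differences from MEF with separate MEF arrays.

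The model was tested on simulated data with the gene means, spreads and group layout of these arrays. The noise was independent between arrays, with 1 spread per gene for all groups and no shift of whole arrays. The shares below hold for such data only. It recovered 54.9% of genes changed by 1.5 on the log2 scale for PH against MEF, 61.7% for iHep against MEF and 79.1% for iHep against PH. At a change of 2 these shares were 85.1%, 86.5% and 93.2%, and at 3 they were 95.5%, 94% and 98.5%. Of unchanged genes 0.096%, 0.084% and 0.132% were called. Probe sets with no symbol or several were left out of the gene comparisons because they name no single gene.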

Results

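Gene expression was measured on 8 single-channel 3' expression arrays of mouse cells in 3 groups. Mouse embryonic fibroblasts (MEFs), flat mesenchymal cells taken from embryos at day 13.5, gave 2 arrays. Induced hepatocyte-like cells (iHeps) are epithelial lines grown from fibroblasts after retroviral delivery of liver transcription factors, and 3 lines at passage 10 gave 1 array each. Line 4a3 received Hnf4a and Foxa3, line 4a3CK the same pair with c-Myc and Klf4, and line 4a1CK received Hnf4a, Foxa1, c-Myc and Klf4. Primary hepatocytes (PH), isolated from the livers of adult male mice by collagenase perfusion and then kept in culture, gave 3 arrays, the one without a number being called PH 3 here. The number of arrays limits the precision of every value, and the p-values measure only the spread between these arrays, because the sources do not say that the MEF or PH arrays came from separate animals or cultures.

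The arrays were not all on the same level. The median log2 value was 4.24 and 4.23 in MEF 1 and 2, 4.45 in 4a3, 4.40 in 4a3CK, 4.43 in 4a1CK, 4.23 and 4.24 in PH 1 and 2, and 5.06 in PH 3. In PH 3, 93.2% of genes lay above the mean of PH 1 and 2. PH 1 and PH 2 were nearly identical, with a standard deviation of 0.159 for their differences across genes, against 0.57 for the MEF pair and 0.549 for PH 1 and PH 3. The bacterial hybridization controls, which do not come from the cells, averaged from 9.28 to 9.47 in PH 3 and the iHep lines and from 8.41 to 8.87 in the MEF arrays and PH 1 and 2. The iHep and MEF groups therefore lie wholly on opposite sides of this split, with PH the only group on both sides. After subtracting array medians the controls of PH 3 stood at 4.22, near MEF 1 and 2 (4.21 and 4.18). PH 1 and 2 were then at 4.42 and 4.63 and the lines at 4.86 to 5.02. The place of PH 3 beside the lines therefore goes with its raised array level. The median difference over all genes was 0.25 for PH against MEF, 0.16 for iHep against MEF and -0.09 for iHep against PH, and the differences below are as deposited, with that shift left in.

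PH against MEF set the target cells against the starting cells. Plasma proteins that hepatocytes secrete were among the genes with the largest rises in PH, and matrix and surface proteins of fibroblasts were among those with the largest falls. Albumin (Alb), the main plasma protein, was higher by 7.84 ± 1.40 on the log2 scale (SE, n = 3 and 2; adjusted p = 0.0123), and Ambp, the precursor of alpha-1-microglobulin and bikunin, by 7.77 ± 0.26 (adjusted p = 3.66e-06). Krt8, a keratin of simple epithelia, was higher by 7.06 ± 0.88 (adjusted p = 0.002). Cdh11, a mesenchymal cadherin, was lower by a log2 difference of -7.54 ± 0.23 (adjusted p = 3.18e-06), and Thy1, a fibroblast surface glycoprotein, by -6.48 ± 0.43 (adjusted p = 8.98e-05). For each of these genes every PH array lay on the same side of both MEF arrays, which the rule for naming genes required. The error of albumin came mostly from the lines, at 9.30 in 4a3 and 3.80 and 4.01 in the others. The MEF arrays read 4.12 and 4.01 and the PH arrays 11.87 to 11.94. The size of the albumin difference hardly moved when an array was left out, but the call (Alb, PH vs MEF) was lost without MEF 1 (adjusted p = 0.0735), MEF 2 (adjusted p = 0.0751) or PH 3 (adjusted p = 0.0721).

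Among the other genes with the largest rises in PH were the fibrinogen chains Fgb (8.95) and Fga (7.48), the iron carrier transferrin (Trf, 7.78), the protease inhibitor Serpina1a (7.77), the retinaldehyde dehydrogenase Aldh1a1 (7.70), the heme carrier Hpx (7.36) and the retinol carrier Rbp4 (7.16). The call for Fgb, at adjusted p = 0.0464, was lost after quantile normalization, at adjusted p = 0.0722. The MEF means of Fgb (2.97), Serpina1a (3.21) and Fga (3.33) lay near the background. Control probe sets that no mouse transcript should bind had medians of 2.825 and 2.878 in MEF 1 and 2. The sizes of the differences for Fgb, Serpina1a and Fga may therefore be lower bounds. Among those with the largest falls were Ptgs2 (-6.90), an enzyme of prostaglandin synthesis, the retinoic acid binding protein Crabp1 (-6.90), the growth factor Igf2 (-6.82), the matrix protein Mgp (-6.76), the matrix protease Mmp3 (-5.95), Gask1b (-5.90), the pentraxin Ptx3 (-5.88) and periostin (Postn, -5.88).

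Of the 29 measured secreted proteins 20 rose and 0 fell in PH, or 23 and 0 adjusted over the list alone (camera adjusted p = 2.2e-22, and adjusted p = 0.0987 with an estimated correlation). Of 14 acute phase proteins 8 rose, or 12 adjusted over the list alone (adjusted p = 2.97e-11, and adjusted p = 0.0987 with an estimated correlation), among them ceruloplasmin (Cp, 6.44), the iron hormone hepcidin (Hamp, 5.73) and Saa2 (5.65). Haptoglobin (Hp) differed by 5.76 without passing, at adjusted p = 0.224. Of 20 liver transcription factors 11 rose, or 12 adjusted over the list alone (adjusted p = 1.07e-13, and adjusted p = 0.159 with an estimated correlation), including Hhex (5.68), Foxa1 (4.33) and the bile acid receptor Nr1h4 (3.79). Of 13 lipoprotein and fatty acid genes 5 rose, or 7 adjusted over the list alone (adjusted p = 4.62e-06, and adjusted p = 0.392 with an estimated correlation), among them Apoc2 (5.12), Apoc1 (5.04) and Mttp (2.70), which loads lipid onto nascent lipoproteins. Of 25 cytochrome P450 and conjugation genes 6 rose and 19 did not pass, with 7 adjusted over the list alone (adjusted p = 1.55e-05, and adjusted p = 0.483 with an estimated correlation). The examples were the sulfotransferase Sult1a1 (4.60), the glucuronosyltransferase Ugt2b5 (4.18) and Cyp3a13 (2.44).

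Of 19 urea cycle and amino acid genes 4 rose in PH, or 5 adjusted over the list alone (adjusted p = 0.00167, and adjusted p = 0.597 with an estimated correlation), with the urea cycle enzymes Cps1 at 2.21 and Asl at 1.62. Of 17 bile acid genes 3 rose, or 4 adjusted over the list alone (adjusted p = 0.0109, and adjusted p = 0.608 with an estimated correlation), with the canalicular exporter Abcc2 at 3.60. Of 10 genes of sugar metabolism 3 rose both over all genes and adjusted over the list alone (adjusted p = 0.0109, and adjusted p = 0.556 with an estimated correlation), with glycogen phosphorylase Pygl at 4.49 and the gluconeogenic enzyme Fbp1 at 3.41. That list did not pass without MEF 2 (adjusted p = 0.0704). Of 34 epithelial junction and keratin genes 15 rose, or 17 adjusted over the list alone (adjusted p = 4.85e-11, and adjusted p = 0.307 with an estimated correlation), including Krt18 (6.76), the desmosomal cadherin Dsg2 (6.64) and E-cadherin (Cdh1, 5.87). Of 9 oxidative stress genes 4 rose, or 5 adjusted over the list alone (adjusted p = 0.00372, and adjusted p = 0.307 with an estimated correlation), with Osgin1 at 6.02 and Gclc, of glutathione synthesis, at 4.16.

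Of 31 fibroblast markers 20 fell in PH, or 23 adjusted over the list alone, with a median of -4.27 (adjusted p = 8.61e-33, and adjusted p = 0.0987 with an estimated correlation), and collagen III (Col3a1) was at -5.85. Of 10 smooth muscle genes 4 fell, or 5 adjusted over the list alone (adjusted p = 4.06e-08, and adjusted p = 0.0987 with an estimated correlation), with the myosin light chain Myl9 at -4.70 and smooth muscle actin (Acta2) at -3.21. Of 10 imprinted growth genes 3 fell, or 7 adjusted over the list alone (adjusted p = 4.76e-11, and adjusted p = 0.0987 with an estimated correlation), with the noncoding RNA Meg3 at -4.45. Of 27 Hox genes 4 fell, and 4 adjusted over the list alone (adjusted p = 3.07e-07, and adjusted p = 0.467 with an estimated correlation), led by Hoxa10 (-3.84) and Hoxc8 (-3.61). Of 29 cell cycle genes 3 fell, and 3 adjusted over the list alone (adjusted p = 1.65e-15, and adjusted p = 0.348 with an estimated correlation). The mitotic kinase Plk1 (-1.52) and the spindle protein Tpx2 (-1.51) were among them. After quantile normalization 9 cell cycle genes fell.

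Of 11 interferon response genes 2 fell in PH, or 3 adjusted over the list alone (adjusted p = 3.49e-07, and adjusted p = 0.467 with an estimated correlation), with Oasl2 at -4.07 and Ifit3 at -3.52. The Ifit3 call (Ifit3, PH vs MEF) was lost without MEF 1, at -1.93 (adjusted p = 0.224). Without MEF 1 the interferon list still passed as lower (adjusted p = 0.0221) although its median was 0.18. Of 16 macrophage markers 2 fell, or 3 adjusted over the list alone (adjusted p = 0.000284, and adjusted p = 0.467 with an estimated correlation), with lysozyme (Lyz2) at -4.18 and Adgre1 at -1.45. Without MEF 2 the macrophage list still passed as lower (adjusted p = 0.0124) although its median was 0.13. Of 13 hypoxia and glycolysis genes 1 fell, the glycolytic enzyme Pkm (-2.05), or 2 adjusted over the list alone (adjusted p = 0.000661, and adjusted p = 0.549 with an estimated correlation). Of 13 fetal liver and progenitor genes 1 rose and 3 fell, or 2 and 3 adjusted over the list alone (adjusted p = 0.0109, and adjusted p = 0.37 with an estimated correlation). Alpha-fetoprotein (Afp), a fetal plasma protein, rose by 6.96 ± 1.58 (adjusted p = 0.0377), whereas Igf2bp3, a fetal RNA-binding protein, was at -3.34. The call for alpha-fetoprotein (Afp, PH vs MEF) was lost after quantile normalization (adjusted p = 0.0744) and when any MEF or PH array was left out. Its error came mostly from the lines, at 8.96 in 4a3 and 2.86 and 2.85 in the others. The MEF arrays read 3.05 and 3.22 and the PH arrays 9.92 to 10.21. Of 13 stellate cell markers 1 fell, and 1 adjusted over the list alone, the growth factor receptor Pdgfrb (-3.59), and the list passed in the falling direction although its median was 0.02, or -0.25 without PH 3, and its mean -0.41 (adjusted p = 0.0139, and adjusted p = 0.467 with an estimated correlation). The fetal liver list did not pass after quantile normalization (adjusted p = 0.0801), without MEF 2 (adjusted p = 0.0525) or without PH 3 (adjusted p = 0.235). The stellate list did not pass without MEF 2 (adjusted p = 0.112) or PH 3 (adjusted p = 0.0997), nor the hypoxia list without MEF 1 (adjusted p = 0.299).

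The lists for cholangiocytes (adjusted p = 0.459), TGF-beta response (adjusted p = 0.0646), Myc targets (adjusted p = 0.0845), inflammation (adjusted p = 0.506), intestine and stomach (adjusted p = 0.92), pluripotency (adjusted p = 0.952), liver endothelium (adjusted p = 0.991), blood cells (adjusted p = 0.781) and p53 response (adjusted p = 0.595) did not pass for PH against MEF. Without MEF 1 the Myc target list (adjusted p = 5.99e-06) and the TGF-beta list (adjusted p = 0.00834) passed as lower in PH, and the inflammation list passed as higher (adjusted p = 0.0409). Without MEF 2 the inflammation list passed as lower (adjusted p = 0.000466). In this comparison the median, mean and test differed in sign for TGF-beta response, inflammation, stellate markers, pluripotency, endothelium, blood cells and p53 response. With an estimated correlation no list passed in any of the 3 comparisons, the lowest adjusted p being 0.0987. That held even for the secreted proteins in PH, of which 20 of 29 rose, with a median of 4.75 (fry adjusted p = 0.000819). Not passing with an estimated correlation therefore does not show that a list was unchanged.

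In all, 1000 of 17097 genes passed for PH against MEF, 577 higher and 423 lower in PH (57.7% higher). After quantile normalization 1139 passed, 520 higher and 619 lower (45.7% higher), and 861 were called in the same direction both ways. Leaving out MEF 1 gave 575 genes, 292 higher and 283 lower, and leaving out MEF 2 gave 612, 267 higher and 345 lower, the lone MEF array then being assumed to vary like the other groups. With the split in the bacterial controls as a block 1007 genes passed, and within the side holding MEF 1 and 2 with PH 1 and 2 the count was 1475. Averaging the nearly identical PH 1 and PH 2, which leaves fewer PH values, gave 688. The block by control level after subtracting array medians gave 686. In submission order MEF 2, PH 3 and the lines form a first set and MEF 1 with PH 1 and 2 a second, and with that order as a block the count was 1276.

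**Figure D1:**
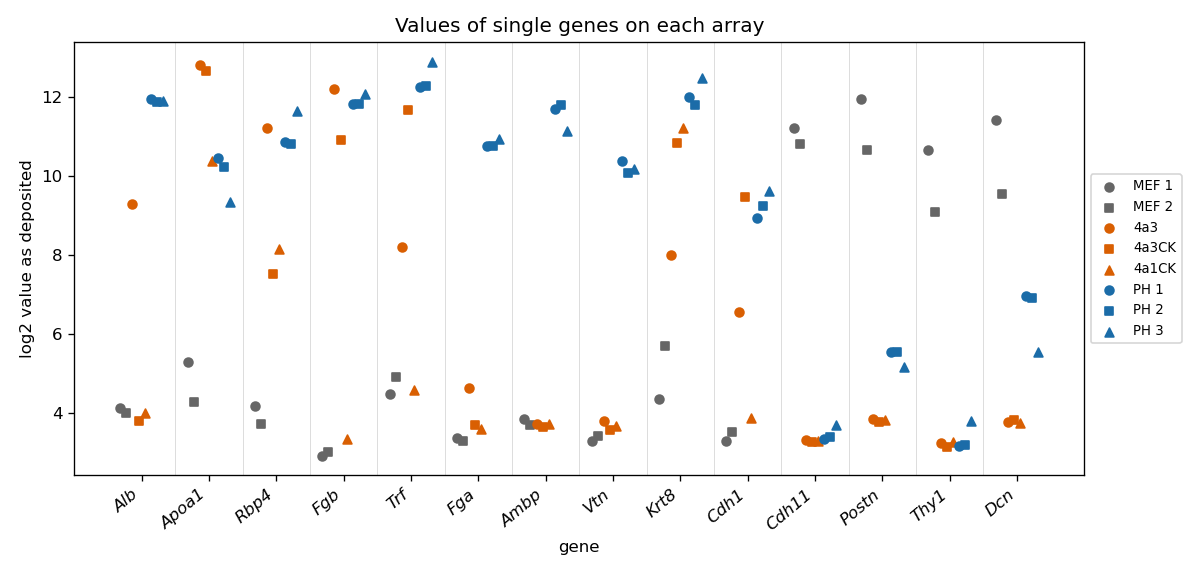
Deposited log2 values of 14 genes on each of the 8 arrays, with MEF arrays in grey, iHep lines in orange and PH arrays in blue; each point is 1 array. Alb is at 9.30 in line 4a3 and at 3.80 and 4.01 in the other lines, while Cdh11, Postn and Thy1 are lower in every line than in either MEF array.

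iHep against MEF set the reprogrammed lines against the starting cells. Matrix and contractile proteins were among the genes with the largest falls in the lines, and epithelial and secreted proteins were among those with the largest rises. Cdh11 fell by 7.72 ± 0.23 on the log2 scale (SE, n = 3 and 2; adjusted p = 5.02e-06), and Postn, a matrix protein of fibroblasts, fell by 7.49 ± 0.36 (adjusted p = 6.57e-05). Apoa1, the main protein of high-density lipoprotein, rose by 7.16 ± 0.72 (adjusted p = 0.000928), and Krt19, a keratin of bile duct and other simple epithelia, by 5.03 ± 0.65 (adjusted p = 0.00325). Each of these 4 genes differed in the same direction in 3 of 3 lines from both MEF arrays, which the rule for naming genes required.

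Other large falls were those of tenascin C (Tnc, -7.18), Col3a1 (-7.14), the proteoglycan decorin (Dcn, -6.69), Thy1 (-6.65), Acta2 (-6.51), Myl9 (-6.20) and Ptx3 (-6.04). Other large rises were those of the tetraspanin Tspan8 (6.99), the selenium-binding proteins Selenbp1 (6.95) and Selenbp2 (5.96), the glutathione transferase Gsta2 (6.08), the G-protein regulator Rgs2 (5.66), the calmodulin-like Calml4 (5.36) and the desmosome-associated protein Perp (5.10). Without MEF 1 the last of these (Perp, iHep vs MEF) stood at 3.36. The transcription factor Mycn rose by 7.37 ± 0.45 (adjusted p = 0.000108), but this came from 1 of its 3 probe sets, which read 11.75, 12.11 and 11.97 in the lines. The other probe sets of Mycn read from 3.30 to 4.11 in the lines.

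Of 31 fibroblast markers 16 fell in the lines, or 22 adjusted over the list alone (camera adjusted p = 6.94e-19, and adjusted p = 0.162 with an estimated correlation). Of 10 smooth muscle genes 5 fell, or 6 adjusted over the list alone (adjusted p = 7.27e-09, and adjusted p = 0.0987 with an estimated correlation). Of 10 imprinted growth genes 3 fell, or 6 adjusted over the list alone (adjusted p = 1.88e-06, and adjusted p = 0.0987 with an estimated correlation), with Meg3 at -4.66. Igf2, at -5.32, did not pass (adjusted p = 0.0905). Of 13 stellate markers 2 fell, and 2 adjusted over the list alone (adjusted p = 0.0138, and adjusted p = 0.467 with an estimated correlation), with Pdgfrb at -3.74 and Rgs5 at -1.16. The list did not pass without MEF 2 (adjusted p = 0.0606). Of 27 Hox genes 1 fell, and 1 adjusted over the list alone (adjusted p = 0.0204, and adjusted p = 0.633 with an estimated correlation).

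Of 11 interferon response genes 7 fell in the lines, or 9 adjusted over the list alone, with a median of -4.86 (adjusted p = 4.03e-11, and adjusted p = 0.307 with an estimated correlation). They included the chemokine Cxcl10 (-5.82) and the interferon-induced genes Ifit1 (-5.43), Rtp4 (-5.41) and Usp18 (-5.31). Of 15 inflammation genes 4 fell, or 1 rose and 8 fell adjusted over the list alone (adjusted p = 7.24e-05, and adjusted p = 0.467 with an estimated correlation), with the chemokines Ccl2 at -5.72 and Ccl7 at -5.16 and Ptgs2 at -4.85. The MEF arrays themselves differed here, MEF 1 standing above MEF 2 by a median of 2.85 over the interferon genes and 1.91 over the inflammation genes. Without MEF 1 the Cxcl10 difference (Cxcl10, iHep vs MEF) was -3.51. Of 16 macrophage markers 3 fell, or 4 adjusted over the list alone (adjusted p = 0.00147, and adjusted p = 0.526 with an estimated correlation), with Lyz2 at -5.40, the protease Ctss at -3.57 and Adgre1 at -1.91. MEF 1 was below MEF 2 by 2 or more for 4 of the 16. The Ctss difference (Ctss, iHep vs MEF) was -5.47 without MEF 1 and -1.68 without MEF 2 (adjusted p = 0.000511 and adjusted p = 0.0306).

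Of 34 epithelial genes 6 rose in the lines, or 9 adjusted over the list alone (adjusted p = 2.35e-05, and adjusted p = 0.467 with an estimated correlation), including Krt8 (4.99) and Krt18 (4.67), with Cdh1 at 3.23 not passing (adjusted p = 0.189). Of 29 secreted proteins 2 rose, Apoa1 and Rbp4 (5.02), and 27 did not pass, with 2 adjusted over the list alone (adjusted p = 0.00155, and adjusted p = 0.467 with an estimated correlation). Fgb, at 5.86, did not pass (adjusted p = 0.161), and neither did Serpina1b, at 3.94 (adjusted p = 0.206). Of 20 liver transcription factors 1 rose, Gata6 (1.85), and 1 adjusted over the list alone (adjusted p = 0.0126, and adjusted p = 0.549 with an estimated correlation). Of 13 hypoxia and glycolysis genes 2 rose, the oxygen-dependent prolyl hydroxylase Egln3 (4.37) and the hypoxia-inducible Ankrd37 (3.01), or 5 adjusted over the list alone (adjusted p = 0.0148, and adjusted p = 0.608 with an estimated correlation). The hypoxia list did not pass after quantile normalization (adjusted p = 0.0689), without MEF 2 (adjusted p = 0.344) or without PH 3 (adjusted p = 0.259). The transcription factor list did not pass after quantile normalization (adjusted p = 0.071), nor the secreted protein list without PH 3 (adjusted p = 0.094).

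No member of the P450 list (adjusted p = 0.274) or of the acute phase list (adjusted p = 0.323) passed in the lines against MEF, where limma gave 3568 of all genes an unadjusted p under 0.05. The lists for bile acids (adjusted p = 0.756), the urea cycle (adjusted p = 0.152), sugar metabolism (adjusted p = 0.0739), lipoproteins (adjusted p = 0.0632), fetal liver (adjusted p = 0.227), cholangiocytes (adjusted p = 0.189) and intestine and stomach (adjusted p = 0.0869) did not pass. Single members of each of these but sugar metabolism passed, including Acox2 (2.46), which shortens bile acid side chains, and the microvillus protein Vil1 (3.22). Of 13 cholangiocyte markers 1 rose and 2 fell. The remaining lists did not pass either, namely TGF-beta response (adjusted p = 0.0503), cell cycle (adjusted p = 0.464), Myc targets (adjusted p = 0.172), pluripotency (adjusted p = 0.148), endothelium (adjusted p = 0.937), blood cells (adjusted p = 0.949), oxidative stress (adjusted p = 0.288) and p53 response (adjusted p = 0.238). In the p53 list 3 of 9 genes rose, and 3 adjusted over the list alone, namely the cell cycle inhibitor Cdkn2a, Trp53inp1 (2.30) and Mdm2 (1.47), which marks p53 for degradation. Without MEF 1 the lists passed for acute phase (adjusted p = 0.00817), sugar metabolism (adjusted p = 0.0227), lipoproteins (adjusted p = 0.0282) and p53 response (adjusted p = 0.0217) as higher, and for TGF-beta response (adjusted p = 0.00834), cell cycle (adjusted p = 0.0118) and Myc targets (adjusted p = 0.000135) as lower. Without PH 3 sugar metabolism and pluripotency passed as higher (adjusted p = 0.0447 for each). Median, mean and test differed in sign for the cell cycle, endothelium and oxidative stress lists.

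In all, 1103 genes passed for iHep against MEF, 339 higher and 764 lower in the lines (30.7% higher). After quantile normalization 692 were higher and 914 lower (43.1% higher), with 1030 called in the same direction both ways. Leaving out 1 array gave 471 genes without MEF 1 (97 higher and 374 lower), 574 without MEF 2 (92 and 482) and 564 without 4a3 (138 and 426). The PH arrays enter through the shared spread, and without PH 3 the count was 1874, 875 higher and 999 lower. Without PH 1 or PH 2 the genes higher in the lines numbered 221 and 204. The bacterial control split separates the groups. The count with it as a block, 2418, rests on PH alone to bridge its sides. A second split, made after subtracting array medians and cut at the middle of the range, gave 62 genes. It set PH 2 with the lines, and PH 1, PH 3 and the MEF arrays on the other side. A cut at the widest gap would have left the lines alone. Submission order as a block gave 1034, 187 higher and 847 lower, with MEF 2 the only MEF array beside the lines.

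iHep against PH asked what still set the lines apart from the target cells. Plasma proteins of the liver were among the genes with the largest falls in the lines. Ambp was lower by a log2 difference of -7.85 ± 0.23 (SE, n = 3 and 3; adjusted p = 1.88e-06), and vitronectin (Vtn), a plasma adhesion protein, by -6.54 ± 0.19 (adjusted p = 1.88e-06). Anxa8, a calcium-dependent membrane-binding protein, was higher by 6.73 ± 0.54 (adjusted p = 0.000246), and Gja1, the gap junction protein connexin 43, by 4.90 (adjusted p = 6.02e-05). Each of these 4 genes differed in the same direction in 3 of 3 lines from every PH array, which the rule for naming genes required.

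Other large falls against PH were those of Fga (-6.83), the complement regulator Cfi (-6.63), the interferon-inducible GTPase Iigp1 (-6.46), Tm4sf4 (-6.21), Alb (-6.20), the C1 inhibitor Serping1 (-6.16), Ccl2 (-6.16) and the thyroid hormone carrier transthyretin (Ttr, -6.14). Other large rises were those of Mycn (6.70), Rgs2 (6.23), Calml4 (5.74), Cdkn2a (5.61), the laminin chain Lamb1 (5.13), the vesicle GTPase Rab27b (5.01), the actin-severing protein gelsolin (Gsn, 4.81) and the actin regulator Eps8 (4.71). The Mycn rise came from the single probe set that was high in the lines. Its other probe sets read from 3.30 to 4.11 in the lines and from 3.37 to 4.61 in PH.

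Of 29 secreted proteins 15 fell in the lines, or 1 rose and 18 fell adjusted over the list alone (camera adjusted p = 6.58e-13, and adjusted p = 0.133 with an estimated correlation). Of 14 acute phase proteins 8 fell, or 9 adjusted over the list alone (adjusted p = 1.3e-08, and adjusted p = 0.124 with an estimated correlation), with Fgl1 at -5.99, Hamp at -5.49 and Saa2 at -5.14. Of 20 liver transcription factors 10 fell, or 12 adjusted over the list alone (adjusted p = 6.63e-09, and adjusted p = 0.307 with an estimated correlation), with Hhex at -4.98, Foxa1 at -3.98 and Nr1h4 at -3.64. Of 25 P450 and conjugation genes 5 fell, or 6 adjusted over the list alone (adjusted p = 0.000733, and adjusted p = 0.549 with an estimated correlation), with Ugt2b5 at -4.42. Of 13 lipoprotein genes 3 fell, or 4 adjusted over the list alone (adjusted p = 0.0139, and adjusted p = 0.554 with an estimated correlation), with Apoc1 at -5.15. Of 17 bile acid genes 2 fell, and 2 adjusted over the list alone (adjusted p = 0.0372, and adjusted p = 0.653 with an estimated correlation), with Abcc2 at -4.72. This list did not pass without PH 3 (adjusted p = 0.0968). Of 9 oxidative stress genes 6 fell, and 6 adjusted over the list alone (adjusted p = 2.91e-05, and adjusted p = 0.154 with an estimated correlation), with Osgin1 at -5.13 and the sulfiredoxin Srxn1 at -3.05.

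Of 29 cell cycle genes 10 rose in the lines and 19 did not pass, or 13 rose and 1 fell adjusted over the list alone (adjusted p = 6.02e-10, and adjusted p = 0.467 with an estimated correlation). Those that rose included Rrm2, of deoxynucleotide synthesis (2.03), and the spindle checkpoint genes Bub1b (1.76) and Bub1 (1.69). After quantile normalization 16 cell cycle genes rose and 0 fell. Of 13 hypoxia and glycolysis genes 5 rose, or 10 adjusted over the list alone (adjusted p = 1.69e-10, and adjusted p = 0.307 with an estimated correlation), with Egln3 at 4.31, Ankrd37 at 3.07 and hexokinase 2 (Hk2) at 2.77. Of 27 Hox genes 1 rose, Hoxc8 (3.46), and 1 adjusted over the list alone, and the list passed (adjusted p = 0.0139, and adjusted p = 0.614 with an estimated correlation), but not after quantile normalization (adjusted p = 0.0725) or without PH 3 (adjusted p = 0.201).

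Epithelial genes went both ways, with 2 of 34 higher and 6 lower, or 2 and 8 adjusted over the list alone (adjusted p = 0.0127 in the falling direction, and adjusted p = 0.602 with an estimated correlation). Krt19 rose by 2.81, while Dsg2 was at -4.18 and the tight junction proteins Ocln at -3.46 and Cldn3 at -3.17. Of 10 smooth muscle genes 3 fell, and 3 adjusted over the list alone (adjusted p = 0.0148, and adjusted p = 0.438 with an estimated correlation), with Acta2 at -3.30. Of 11 interferon genes 3 fell, or 4 adjusted over the list alone (adjusted p = 0.000661, and adjusted p = 0.549 with an estimated correlation), and of 15 inflammation genes 4 fell, or 8 adjusted over the list alone (adjusted p = 0.00167, and adjusted p = 0.549 with an estimated correlation). Usp18 (-4.95), Rtp4 (-4.94) and the chemokine Ccl20 (-3.87) were among them.

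Fibroblast markers did not pass as a list between the lines and PH (adjusted p = 0.113), with 3 of 31 higher and 3 lower, and 3 and 3 adjusted over the list alone. The mesenchymal transcription factor Twist1 (2.75) and the calcium-binding protein S100a4 (2.85) were higher in the lines and N-cadherin (Cdh2, -4.41), which hepatocytes also express, was lower. The lists for the urea cycle (adjusted p = 0.0702), sugar metabolism (adjusted p = 0.35), fetal liver (adjusted p = 0.0692), cholangiocytes (adjusted p = 0.0547), TGF-beta response (adjusted p = 0.863), intestine and stomach (adjusted p = 0.0702), Myc targets (adjusted p = 0.937), pluripotency (adjusted p = 0.0672), imprinted genes (adjusted p = 0.197), macrophages (adjusted p = 0.431), endothelium (adjusted p = 0.943), stellate cells (adjusted p = 0.506), blood cells (adjusted p = 0.701) and p53 response (adjusted p = 0.0929) did not pass. After quantile normalization the urea cycle list passed as lower (adjusted p = 0.0356) and pluripotency as higher (adjusted p = 0.0112), as did pluripotency without PH 3 (adjusted p = 0.0129). Without MEF 1 the cholangiocyte list passed as lower (adjusted p = 0.0489). Median, mean and test differed in sign for Myc targets, blood cells and p53 response.

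In all, 1219 genes passed for iHep against PH, 254 higher and 965 lower in the lines (20.8% higher). After quantile normalization 607 were higher and 736 lower (45.2% higher), with 924 called in the same direction both ways. Leaving out 4a3 gave 604 genes (119 higher and 485 lower), leaving out PH 1 gave 576 (81 and 495) and leaving out PH 2 gave 610 (83 and 527). Leaving out PH 3 gave 1806, 884 higher and 922 lower, and averaging the nearly identical PH 1 and PH 2 gave 588. With the bacterial control split as a block 2951 passed and with the second split, after subtracting array medians, 188. With submission order as a block the count was 1306, 108 higher and 1198 lower. In the first of these splits and in the submission order, PH 3 is the only PH array beside the lines. In the second split that array is PH 2.

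The position of the lines between MEF and PH was measured for each of the 1000 genes that passed between those groups, with MEF at 0% and PH at 100%. Over the 577 genes higher in PH the median position was 30.4%, with quartiles of 7.3% and 64.7%, and 199 genes lay past 50%. Over the 423 genes lower in PH the median was 95.5%, with quartiles of 62.4% and 109%, and 343 lay past 50%. Medians for genes higher in PH were 30.6% in 4a3, 28.9% in 4a3CK and 28.8% in 4a1CK, and for genes lower in PH 98.7%, 99.3% and 95.2%. After quantile normalization the medians were 34.8% and 87.2%. Because the genes were chosen for a difference from the same MEF arrays and PH arrays, these medians carry no test, and the median over all 1000 genes was 55.7%.

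**Figure D2:**
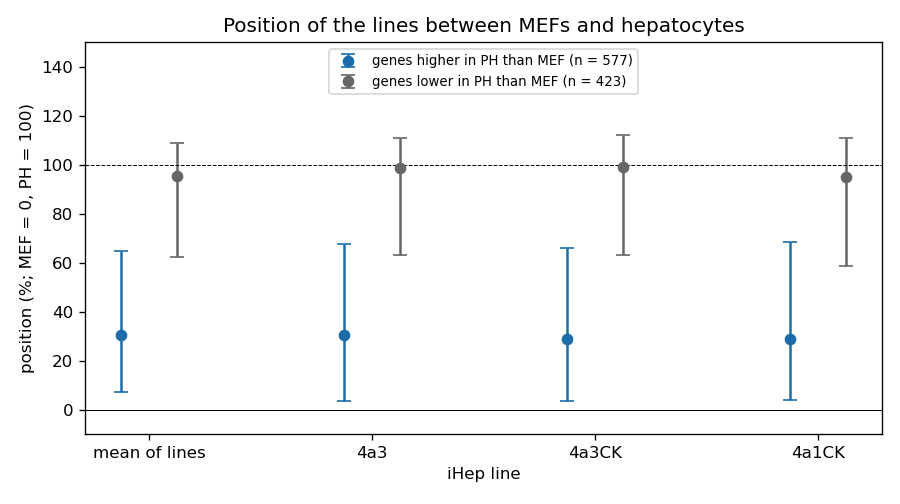
Position of the mean of the lines and of each line between MEF (0%) and PH (100%) on the log2 scale, for genes higher in PH (blue, n = 577) and lower in PH (grey, n = 423); points are medians over genes and bars run from the lower to the upper quartile. For the mean of the lines the blue median is at 30.4% and the grey median at 95.5%.

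Of the genes higher in PH than in MEF, 127 were also higher in the lines than in MEF and 7 were lower, while 312 were lower in the lines than in PH. Of the genes lower in PH, 303 were also lower in the lines and 3 were higher, and 71 were above PH in the lines. Independent lists of these sizes would share 11.4 and 18.9 genes. Both overlaps use the same 2 MEF arrays. In a check chosen after seeing the data, each comparison took its own MEF array, a lone array assumed to vary like the other groups. With MEF 1 for PH and MEF 2 for the lines 29 genes were higher in both, where independent lists would share 1.51, and 173 were lower, against 7.55. With the arrays exchanged 32 were higher, against 1.57, and 165 lower, against 7.98. The differences from MEF correlated at 0.61 across genes, which are not independent replicates, against 0.6 in simulations with unchanged groups that shared the MEF arrays, while their covariance was 0.529 against 0.0928. With separate MEF arrays the covariance was 0.466 and 0.43.

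Genes that set the lines apart from both MEF and PH numbered 361, of which 81 were higher and 280 lower than both. The higher genes included Mycn, Rgs2, Calml4, Rab27b (5.02 above MEF), Ccdc68 (4.78), Egln3 and the sialomucin Podxl (4.72). Mycn was again read by the single probe set that was high in the lines, which its other probe sets did not follow. The lower genes included Ccl2, Usp18, Rtp4, the interferon-induced Samd9l (a log2 difference of -4.67 from MEF), the growth factor carrier Igfbp3 (-5.62), the scaffold protein Akap12 (-4.12), the small heat shock protein Cryab (-5.07) and the actin crosslinker filamin A (Flna, -4.73). After quantile normalization 242 were higher and 236 lower. The count was 153 without MEF 1, 200 without MEF 2, 140 without 4a3, 169 without PH 1, 169 without PH 2 and 755 without PH 3, of which 394 were higher and 361 lower. Without 4a3CK 147 were higher, and without 4a1CK 159 were lower. The count was 1405 with the bacterial control split as a block and 15 with the split after subtracting array medians. After that subtraction the controls stood at 4.86 to 5.02 in the lines and at 4.18 to 4.63 in all other arrays. For these genes a difference of the lines therefore cannot be told apart from a difference in hybridization.

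The transduced factors were read by probe sets that may lie outside the sequence the vectors carried, so low values say nothing of the transgenes. High values do not tell a transgene from the cell's own gene. Hnf4a, a nuclear receptor of hepatocyte identity, read 9.59 in 4a3CK, 6.04 in 4a3 and 5.51 in 4a1CK, against 5.65 and 5.62 in MEF and 9.48 to 9.78 in PH. Its differences were 1.41 for the lines against MEF (adjusted p = 0.471) and 3.97 for PH against MEF (adjusted p = 0.0585). The lines differed from PH by -2.56 (adjusted p = 0.138). Most of the error in all of these comparisons came from the lines, where 4a3CK stood apart. Foxa1 and Foxa3, which open liver chromatin, differed from MEF by 0.35 and 0.28 in the lines without passing, while Foxa3 rose by 2.73 in PH. Klf4 fell in PH against MEF by a log2 difference of -2.15 and was 3.17 higher in the lines than in PH. It read 10.60 in 4a3, which did not receive Klf4, and 9.43 and 9.56 in 4a3CK and 4a1CK, against 8.56 and 9.12 in MEF. Myc differed from MEF by 1.08 in the lines and 1.57 in PH without passing. As a list, the 5 factors passed for PH against MEF, with 2 higher and 1 lower, or 4 and 1 adjusted over the list alone (adjusted p = 0.0253, and adjusted p = 0.467 with an estimated correlation). They did not pass for the lines against MEF (adjusted p = 0.177) or against PH (adjusted p = 0.114), though without PH 3 they passed as lower than PH (adjusted p = 0.0398).

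**Figure D3:**
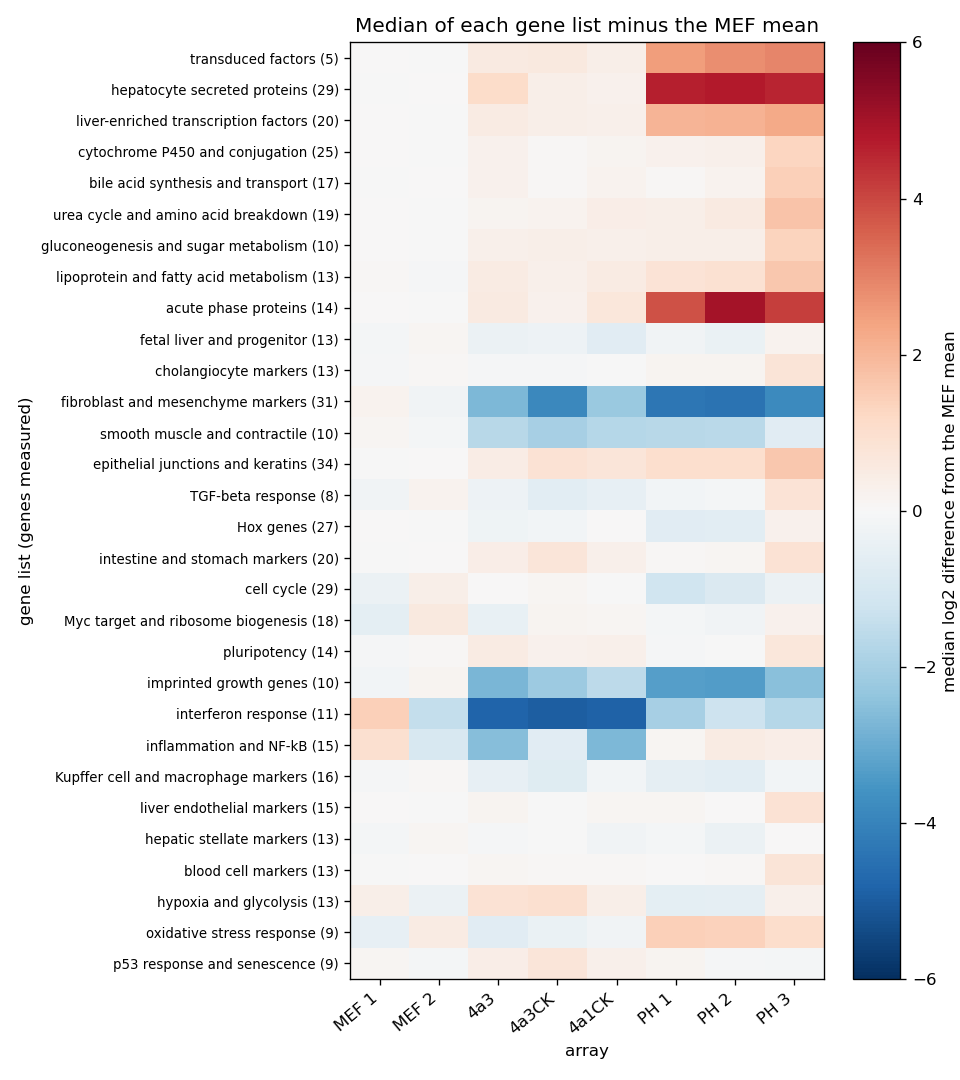
Median log2 value of each of the 30 gene lists on each of the 8 arrays minus the mean of the MEF arrays, with the number of genes measured in brackets and colour from -6 (lower) to 6 (higher). The fibroblast list is at -2.71 in 4a3, -3.85 in 4a3CK and -2.21 in 4a1CK, and the secreted protein list at 1.09, 0.37 and 0.27.

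4a3CK against 4a3 sets the line with c-Myc and Klf4 against the line with the same liver factors alone. With 1 array per line no test was made. Of 29 secreted proteins 2 were higher by 2 or more in 4a3CK, including Kng1 (4.40), the kinin precursor, and 5 were lower. Of 20 intestine and stomach genes 5 were higher and 0 lower. The differences for 4a3CK minus 4a3 were 9.25 for the mucus-associated Clca1, 8.22 and 6.22 for the gastrokines Gkn2 and Gkn1, 6.82 for the matrix protein Efemp1, 6.29 for Col10a1, 6.04 for Gna14 and 5.48 for Aldh1a1. They were -7.06 for Ms4a4b, -6.74 for the pyruvate dehydrogenase kinase Pdk4, -6.73 for the amino acid transporter Slc38a4, -6.33 for lipocalin 2 (Lcn2), -6.14 for Igf2, -6.10 for Afp, -6.03 for Pwwp3b and -5.50 for Alb. Hnf4a differed by 3.55, Myc by 0.90, Klf4 by -1.17, Foxa1 by -0.32 and Foxa3 by 0.05. For Clca1, Gkn2, Pdk4 and Hnf4a, 4a3CK differed by similar amounts from 4a1CK, which also received c-Myc and Klf4. Those differences therefore cannot be credited to c-Myc and Klf4 alone. Over the 29 secreted proteins the median difference was -0.24, at percentile 0.04 of 10000 random lists matched on level, and over 18 Myc target and ribosome biogenesis genes it was 0.80, at percentile 100, with the pyrimidine enzyme Cad at 1.82 and the RNA helicase Ddx21 at 1.68. The intestine and stomach list stood at 0.20 (percentile 100), the fetal liver list at -0.38 (percentile 0.2) and the TGF-beta list at -0.56 (percentile 0.16). Lists of cells not looked for in these lines also reached low percentiles, macrophage markers at -0.17 (percentile 1.03) and liver endothelium at -0.15 (percentile 1.77), as did p53 response at -0.35 (percentile 1.92). A percentile over genes of single arrays therefore does not show a difference particular to a list.

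A difference of at least 2 was seen for 381 genes between these lines, 232 higher and 149 lower in 4a3CK. Arrays of the same group differed by as much at 239 genes for the MEF pair, 2 for PH 1 and 2, 257 for PH 1 and 3, 247 for PH 2 and 3 and 226 for the lines 4a1CK and 4a3, which differ in more factors. After quantile normalization 4a3CK and 4a3 differed at 384 genes, the MEF pair at 237, the PH pairs at 2, 111 and 118 in that order, and 4a1CK and 4a3 at 244. Line 4a3 also had the largest 3' to 5' difference among the arrays for the beta-actin control probe sets, a sign of RNA quality, at 1.43 against 0.51 to 0.94 elsewhere. For the Gapdh control probe sets it stood at 0.314, below MEF 2 (0.575), PH 1 (0.689) and PH 2 (0.719).

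4a3CK against 4a1CK sets Foxa3 against Foxa1 beside the same other factors, again without replicates. Of 20 intestine and stomach genes 6 were higher by 2 or more in 4a3CK and 1 lower, and of 31 fibroblast markers 0 were higher and 8 lower. The differences for 4a3CK minus 4a1CK were 9.20 for Clca1, 8.34 for Gkn2, 8.07 for the trypsin inhibitor Spink1, 7.56 for Fgb, 7.27 for the chaperone clusterin (Clu), 7.10 for Trf and 6.88 for the mucosal peptide Tff3. They were -7.14 for the prolactin family member Prl2c2, -6.44 for Pdk4, -6.12 for the proteoglycan biglycan (Bgn), -6.08 for Col4a5, -6.02 for Mpzl2, -5.85 for the protease Htra1, -5.57 for the oxidase Nox4 and -5.54 for Adssl1. Hnf4a differed by 4.08, Myc by 0.90, Klf4 by -0.13, Foxa1 by -0.15 and Foxa3 by 0.07. For Clca1, Gkn2, Pdk4 and Hnf4a, 4a3CK differed by similar amounts from 4a3, which also received Foxa3. Those differences go with the single line 4a3CK and cannot be credited to Foxa3 alone. The fibroblast list had a median of -0.47 (percentile 0 of the random lists), with the collagen crosslinker Lox at -4.99, and the imprinted list -0.76 (percentile 0.09), while the intestine and stomach list stood at 0.28 (percentile 100). The secreted protein list stood at -0.08 (percentile 10.5), with 7 of 29 higher by 2 or more in 4a3CK and 1 lower, the lipoprotein component Apoc3 (-5.12), and the Myc target list at 0.18 (percentile 84.1). A difference of at least 2 was seen for 541 genes, 307 higher and 234 lower in 4a3CK, and for 534 after quantile normalization.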

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

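The test by other splits of the arrays was set before its result was seen, and no test in this part was chosen afterwards. A signal appeared in the 16139 probe sets that carry no single gene symbol and that no comparison of genes used. For PH against MEF 328 of them passed, 191 higher and 137 lower in PH, and 325 passed after quantile normalization. For iHep against MEF 351 passed, 132 higher and 219 lower in the lines, and 737 after quantile normalization. For iHep against PH 418 passed, 108 higher and 310 lower, and 637 after quantile normalization.

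The 3 iHep and 3 PH arrays can be split into groups of 3 in 10 ways. The real split gave 1219 genes and was the 1 split with as many, the highest other split giving 0. With 10 splits the share cannot fall under 0.05. Every other split mixed iHep and PH arrays within its groups, so differences between iHep and PH entered the spread and left few genes able to pass. The low counts of those splits are therefore no separate evidence for the real split.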

How the results depend on the processing

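The blocks by bacterial controls, the averaging of PH 1 and 2, quantile normalization without PH 3 and the crossed pairing were chosen after seeing the data. Counts are given for PH against MEF, iHep against MEF, iHep against PH and genes apart from both, and the cause of a change was not tested unless given. Leaving out 1 array gave 575 to 1156, 471 to 1874, 576 to 1806 and 140 to 755 genes, and a position of 56.1% to 80.8%; the lone MEF array left when the other is omitted is assumed to vary like the other groups. The lowest counts came without MEF 1 (575 and 471), PH 1 (576) and 4a3 (140), and the highest without 4a3CK (1156) and PH 3 (1874, 1806 and 755). An adjusted p under 0.01 gave 522, 389, 476 and 100 and a log2 difference of at least 2 gave 617, 545, 458 and 112, both fewer by construction, and the former a position of 63.7%. The position was 53.1% with the mean of probe sets, 67.1% after quantile normalization, 68.5% after subtracting array medians, 58.3% with each line as its own group and 59.2% with a block by submission order. With a block by bacterial controls iHep against MEF gave 2418, iHep against PH 2951 and genes apart 1405, with a position of 59.0%. The second block, after subtracting array medians and with PH 2 beside the lines, gave 62, 188 and 15. Averaging PH 1 and 2 gave 588 for iHep against PH and 166 apart, and quantile normalization without PH 3 gave 1800 for iHep against MEF and 707 apart. At a difference of at least 1 the line pairs differed at 1677 genes (4a3CK and 4a3) and 1835 (4a3CK and 4a1CK), more by construction. The inflammation list passed in opposite directions for PH against MEF without MEF 1 (median 1.29, adjusted p = 0.0409) and without MEF 2 (-0.41, adjusted p = 0.000466), and a gene reversed (Foxa1, iHep vs MEF) with the block by bacterial controls (-1.85, adjusted p = 0.00725). Of 390 results for named genes, quantile normalization left 367 the same, 9 now passing and 14 no longer passing, and leaving out 1 array ended from 8 calls (4a3CK) to 56 (PH 1). Of 90 list results, an estimated correlation left 43 the same and ended 47. With fry, which compares a list with no other genes, 57 stayed the same, 22 no longer passed, 3 now passed and 8 that passed neither way differed in sign. Among the 4 arrays numbered 1 and 2 of MEF and PH, 1475 genes passed without a block, 900 with replicate number as a block and 1307 with the numbers crossed, and 2 pairs are too few to say that the numbers pair the samples. Signal over background limits dim genes: leaving out 1717 genes under the percentile 40 value left the 3 tested counts within 1.5 times.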

Other observations

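The tests of the albumin pattern and of the interferon pattern in this part, and the look at the MEF pair and the probe sets of Mycn, were chosen after the results had been seen. The MEF arrays differed from each other in immune genes. MEF 1 was above MEF 2 by 8.34 on the log2 scale for the acute phase gene Saa3, 6.74 for Lcn2, 6.10 for Hp, 5.94 for the interferon-induced chemokine Cxcl9, 5.73 for Iigp1 and 5.05 for the cytokine Il6. It was below MEF 2 by a difference of -4.35 for Bex1, -3.79 for Ctss, -3.47 for Perp, -3.31 for the lipid carrier Apoe and -3.24 for the fetal surface protein Dlk1. The median difference was 2.85 for the interferon list, 1.91 for the inflammation list, -1.22 for Myc targets and -0.99 for oxidative stress genes.

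PH 3 lay above PH 1 and 2 at most genes. If separate background correction or normalization of that array made the shift, control probe sets that no mouse transcript should bind would move with the genes, and they did. Their median shift was 0.684 over 23 probe sets (from 0.589 to 1.828), beside 0.707 over all genes, so separate processing is a candidate explanation, and no biological explanation was tested because the sources name no difference between the PH samples. A further test asked whether the shift accounts for most of the low count for PH against MEF, and the count was 1007 without PH 3 and 1000 with it. Leaving out PH 3 also removes an array, and fits of that size that kept PH 3, without PH 1 or without PH 2, gave 686 each, so a part of the low count may go with PH 3, whereas with all arrays kept the count was 1139 after quantile normalization and 1153 after subtracting array medians, which argues against an offset as the source of most of it.

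In line 4a3 albumin read 9.30 and alpha-fetoprotein 8.96, while both were near the MEF level in the other lines. Hepatocyte cells or RNA in that sample would bring all abundant hepatocyte transcripts in like shares. But 3 of 12 others lay far below albumin's share of 16.1% of the PH level, Ambp at -0.018%, Vtn at 0.31% and Fga at 0.831%. Ambp read 3.72 in 4a3, against a mean of 3.78 in MEF and 11.55 in PH. In contrast, Apoa1 (716%), Fgb (122%) and Rbp4 (108%) stood above the PH level. The 3 low shares met the bound of 3 set for that test with none to spare, and the median share of the 12 was 18%, near albumin's. A single unreliable probe set is argued against for alpha-fetoprotein, where 2 of 4 other probe sets were at least 2 above MEF, but stays open for albumin, which has 1 probe set, since 9 other secreted proteins were at least 2 above MEF in 4a3, and 9, not all of them the same, in 4a3CK, whose albumin was at the MEF level. Which secreted proteins a line expresses may therefore differ from line to line, 4a3CK standing at 57.9% of the PH level for Trf and 54.6% for Serpina1b, with the part of c-Myc and Klf4 untested on 1 array per line.

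Interferon-stimulated genes were lower in the lines than in MEF. High activity in MEF 1 alone is argued against by a median of -3.51 against MEF 2 (-5.93 against MEF 1), with 9 of 11 genes lower in all 3 lines than in MEF 2. An offset of whole arrays is argued against by the array medians, which were higher in the lines (4.40 to 4.45) than in MEF (4.23 and 4.24). Subtracting them could therefore not lessen the fall, and the median of -4.92 after it is no separate test. Macrophages in the MEF samples as a source cannot be told apart from the fibroblasts' own expression, since the macrophage markers, none of which stood on another list, differed by a median of -0.13 between MEF 1 and 2, with 4 of 16 lower by 2 or more in MEF 1, while the interferon genes differed by 2.85. Lower interferon activity in the lines may therefore reflect the lines themselves or the state of the MEF cultures, and 9 of 11 genes were also lower in all lines than in every PH array.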
